A study of Mus musculus with 9 samples.

How the data were processed

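Total RNA of 9 samples of sorted mouse leukemia stem cells was hybridised to Illumina bead arrays after biotin labelling, per the labels' protocols. A hairpin against luciferase was the control in 3 samples, hairpin 94 against Csnk1a1 was used in 3 and hairpin 97 in 3. The groups and replicate numbers (1 to 3 for Luc and hairpin 94, 4 to 6 for hairpin 97) come from the sample titles. The authors deposited an intensity per probe and array, an average bead signal per the file headers. That the background was left in and that arrays were not brought to a common scale was worked out from the values. They also deposited a detection p-value per probe and array. The deposited series matrix holds log2 values whose scale and direction were worked out from the data: within each array they had the rank order of the signals (smallest rank correlation 1), and all columns shared the same distribution, with a median of 6.612 in each, as after quantile normalization. They were not centred per gene. The software and settings behind these values are not given in the sources used here, nor is a slide or scan date, so no batch could be tested.

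The signals were background corrected and normalized with neqc of limma 3.58.1 in R 4.3.3, which infers the negative control signal from the detection p-values, adds an offset of 16, applies quantile normalization and takes log2. A probe was kept if its detection p was under 0.05 on at least 3 of the 9 arrays. This left 13641 of 45281 probes. The platform annotation table gave 34885 probes 1 gene symbol, 18 several and 10378 none listed. Symbols were matched to the gene table of assembly GRCm38.p6 through gene numbers, which found 34807. Probes without a single symbol were left out of the gene tests, among them 1958 detected ones. A gene was represented by its detected probe with the highest mean, which gave 8027 genes, of which 2669 had other detected probes. Fold changes depend on the offset and on the background correction, which both shrink or stretch changes of dim probes.

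A mean per group was fitted to all 9 arrays with lmFit, and 4 contrasts were tested with eBayes and Benjamini-Hochberg adjustment at an adjusted p under 0.05: each hairpin against Luc, the mean of both against Luc (the main comparison), and hairpin 97 against hairpin 94. Every adjusted p of a gene is from this limma fit. For a probe detected on no Luc array a bound is given in place of a fold: the mean of the knockdown arrays against the mean, per Luc array, of the higher of the lowest signal among detected probes and the probe's own. Where only some arrays of a group detected a probe, their number is given. A total of 29 gene lists was fixed before the data were examined, and the 24 with at least 5 measured genes were tested with camera at a preset correlation of 0.01, with camera at the correlation estimated from the arrays, and with fry, adjusted over the lists within each contrast. The lists share some members. The estimated correlation lay below the preset for the neutrophil (-0.00213), p53 (-0.0157), interferon (-0.0301) and T and NK lists (-0.11). It lay above the preset for the mast cell, basophil and eosinophil list (0.0468). Where it lay below, a call lost with the estimate was not lost through a stronger correlation. The genes named were chosen by a rule fixed at the same time. In the main comparison it takes the target, the 10 largest rises and 10 largest falls past the threshold whose 6 knockdown arrays all lie on the same side of the 3 Luc arrays, and up to 4 leading members of each list. For single hairpins and between hairpins it takes the 5 largest in each direction. Not every gene that the rule takes is named, and the examples within a list were picked after their values were seen. Genes outside the rule were also named after their values were seen, as well-known members of their lists: S100a8, Lcn2, Ltf, Chil3, Mpo, Cebpe, Elane, Prtn3, Ctsg, Csf3r, Ddb2, Cdkn1a, Mdm2, Ccng1, Cd80, Kit, Hoxa9, Meis1, Csnk2a2, Gins2, Aurka, Aurkb, Cdk1, Plk1, Birc5, Nusap1, Ccne2 and Oas1g. Counts of genes that rose include genes undetected on all Luc arrays, whose fitted changes are not bounds.

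Results against Luc share the same 3 control arrays, so the agreement of the hairpins was set beside 100 simulations of unchanged groups against shared controls. The limma fit and camera were tested on simulated values with the real gene means and spreads, drawn independently for each gene. Of 8027 genes 200 were changed. Background correction, normalization, the detection filter, probe choice and a brightness difference between groups were not simulated, so the test says nothing about them. For the mean of both hairpins the limma fit recovered 90% of changes of 1 on the log2 scale and 27% of changes of 0.5, with 9 false calls among 126. For hairpin 97 against hairpin 94 it recovered 80% and 13%, with 4 false calls among 97. In a simulated shift of 1 list, camera called that list and 0 others.

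Alternatives fixed before the data were examined were no detection filter, probes detected on all arrays, every detected probe tested, no background correction, median scaling, the series matrix values, fits to only the groups compared, a trended and robust variance, array weights, each array left out in turn, and the replicate number as a block for hairpin 94 against Luc. Median scaling over the probes detected on all arrays, cyclic loess, the mean of all detected probes of a gene, its other detected probes alone, and the number of detected probes as a covariate were added after seeing the data.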

Results

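Gene expression was profiled on bead arrays in leukemia stem cells of the mouse. The cells carried the MLL-AF9 oncogene, a fusion that drives acute myeloid leukemia, and were sorted by surface markers and dye exclusion from the bone marrow of serially transplanted animals. In 3 samples the cells carried a control hairpin RNA against luciferase (Luc), and in 2 further groups of 3 samples each they carried a hairpin against Csnk1a1, numbered 94 or 97. Csnk1a1 encodes casein kinase 1 alpha, a kinase that limits both beta-catenin and p53 activity. The series title names p53-dependent killing, so the comparisons ask which genes differed between knockdown and control cells, whether p53-activated genes were among them, and whether the hairpins differed. Each array reported a signal and a detection p for 45281 probes, of which 13641 were detected on at least 3 of the 9 arrays, and 8027 genes were tested. The labels do not say whether the samples of a group came from separate mice or cultures, so the p-values measure the spread between these samples only. With 3 arrays per group, the number of arrays limits the precision, and the median standard error of a log2 fold change was 0.148 for knockdown against Luc.

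The targeted gene could not be measured. Csnk1a1 had 1 probe, which was detected on 0 of the 9 arrays, with detection p between 0.293 and 0.862, so the arrays do not check the knockdown and no fold change is given. Among 6 measured relatives in the list of casein kinase 1 and 2 genes, 3 rose and 2 fell with knockdown, and the same counts held adjusted over the list alone. Their median log2 fold change was 0.191, or 0.0602 with the 2 genes undetected on all Luc arrays at their lower bound. Csnk1d, a close relative of the target, fell by 0.88 on the log2 scale (SE 0.119, adjusted p = 0.0003812 by limma), and of its 4 other detected probes, 2 also passed as lower, with -0.73 and -0.63, while the others gave 0.13 and 0.46. Before normalization the signal of its brightest probe was not lower with knockdown, at 387.5 to 422.4 on Luc arrays and 426.1 to 652.8 on knockdown arrays. The fall is therefore relative to the other probes of each array. Csnk1e fell by 0.69 (adjusted p = 0.04643), with 0.27 from its other probe, and Csnk2a2, a catalytic subunit of casein kinase 2, rose by 0.52 (adjusted p = 0.03189), with 1.01 from its other probe, which passed too.

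The Luc arrays were dimmer than the knockdown arrays. A Luc array detected 9956 ± 602 probes (SD, n = 3), a hairpin 94 array 13507 ± 673 (SD, n = 3) and a hairpin 97 array 13544 ± 601 (SD, n = 3). The mean signal was 130.3 ± 1.27 (SD, n = 3) for Luc, 183.5 ± 14.45 (SD, n = 3) for hairpin 94 and 186 ± 13.65 (SD, n = 3) for hairpin 97. Knockdown arrays exceeded Luc arrays by 3570 detected probes and by 54.48 signal units, with a two-sided exact permutation p of 0.0119 for each, the smallest that 84 splits can give. Brightness was therefore confounded with knockdown in the comparisons with Luc, beyond what a linear covariate can remove, whereas the hairpin groups were about equally bright. Changes are given after quantile normalization, relative to the arrays as a whole.

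**Figure D1:**
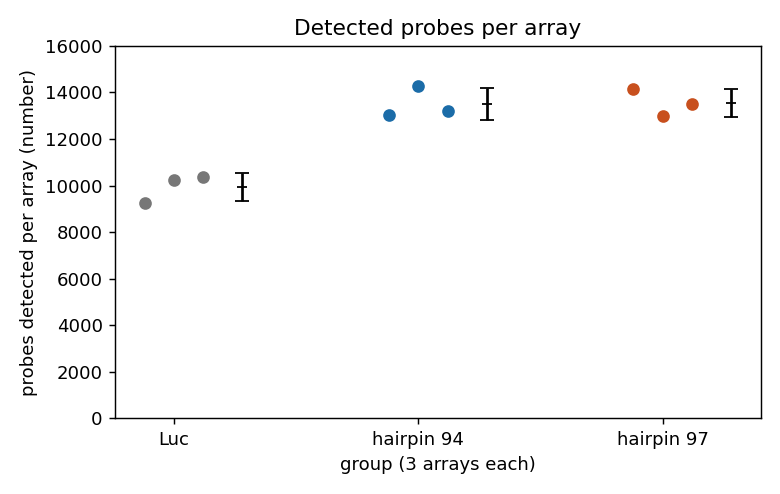
Number of probes detected per array (vertical axis) in the 3 groups, with a point per array and the mean ± SD of 3 arrays beside the points. All Luc arrays lie at or below 10347 probes and all knockdown arrays at or above 12969.

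Genes of the list of neutrophil granules and granulocyte maturation were higher in knockdown cells as a group. Of 20 measured members of this list, 14 rose and 0 fell with the mean of both hairpins against Luc, over all genes tested and adjusted over the list alone alike, with a median log2 fold change of 0.678, or 0.632 with the 2 genes undetected on all Luc arrays at their lower bound. The median was 0.39 without background correction, 0.348 with the series matrix values, 0.43 with scaling over the probes detected on all arrays and 1.87 with scaling over all probes. At an unadjusted p under 0.05 by limma 14 were higher and 1 lower. Camp, the precursor of the antimicrobial cathelicidin peptide, rose by 2.85 (SE 0.2795, adjusted p = 0.0001185), with its probe detected on 2 of the 3 Luc arrays. S100a9, a subunit of the calprotectin complex of neutrophils, rose by 1.98 (SE 0.1528) and Ngp, a neutrophilic granule protein, by 1.91 (SE 0.147), each with an adjusted p of 6.366e-05. S100a8, the partner of S100a9, rose by 0.92, and Lcn2, an iron-scavenging protein of the secondary granules, by 1.02. Fcnb, a ficolin of myeloid cells, rose by 1.25 (detected on 2 of the 3 Luc arrays) and Cebpe, a transcription factor needed for secondary granules, by 0.39. Ltf (lactoferrin) and Chil3 were detected on 0 of the 3 Luc arrays and on all 6 knockdown arrays, and were at least 1.48-fold and 1.14-fold higher, counted from the detection floor of the Luc arrays. Mpo, the myeloperoxidase of primary granules, rose by 0.66. The primary granule proteases Elane (0.22), Prtn3 (-0.14) and Ctsg (-0.19) did not pass, and neither did Csf3r, the receptor for the granulocyte growth factor (-0.58, SE 0.2486, detected on 2 of the 3 Luc arrays and on 5 of the 6 knockdown arrays). Elane passed in 4 of the alternatives, among them no background correction (0.224), Ctsg as lower without background correction (-0.197) and with the series matrix values (-0.213), Csf3r as lower with cyclic loess (-0.609) and with scaling over the probes detected on all arrays (-1.22), and Prtn3 as lower with the latter (-0.371). With hairpin 97 alone, Csf3r (-0.89) and Ctsg (-0.34) passed as lower.

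The list as a whole stood above the other genes with limma's camera test (adjusted p = 0.000457 over 24 lists, preset correlation 0.01). The call did not hold when camera estimated the correlation from these arrays (camera adjusted p = 0.0827). That estimate was -0.00213, below the preset 0.01, so a stronger correlation between the genes did not end the call. Against Luc, hairpin 94 alone gave an adjusted p of 4.28e-05 (0.0477 with an estimated correlation) and hairpin 97 alone 0.00301 (adjusted p = 0.139 with an estimated correlation), with medians of 0.806 and 0.681. Over only the other probes the hairpin 97 call ended (median 0.701). With the number of detected probes as a covariate the list kept its camera call with the preset correlation, with medians of 0.666 for the mean of both hairpins, 0.72 for hairpin 94 and 0.623 for hairpin 97. Of 9 measured monocyte and macrophage genes 4 also rose and 0 fell in limma, with a median of 0.335 and a fry adjusted p of 0.000317. Camera did not set this list apart from other genes (adjusted p = 0.334, and 0.48 with an estimated correlation). The Luc arrays, against which these genes rose, had 3570 fewer detected probes. The 7 genes of the list with other detected probes had 11 such probes, all of them higher with knockdown, with a median of 0.69 against 0.20 for such probes of all genes.

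**Figure D2:**
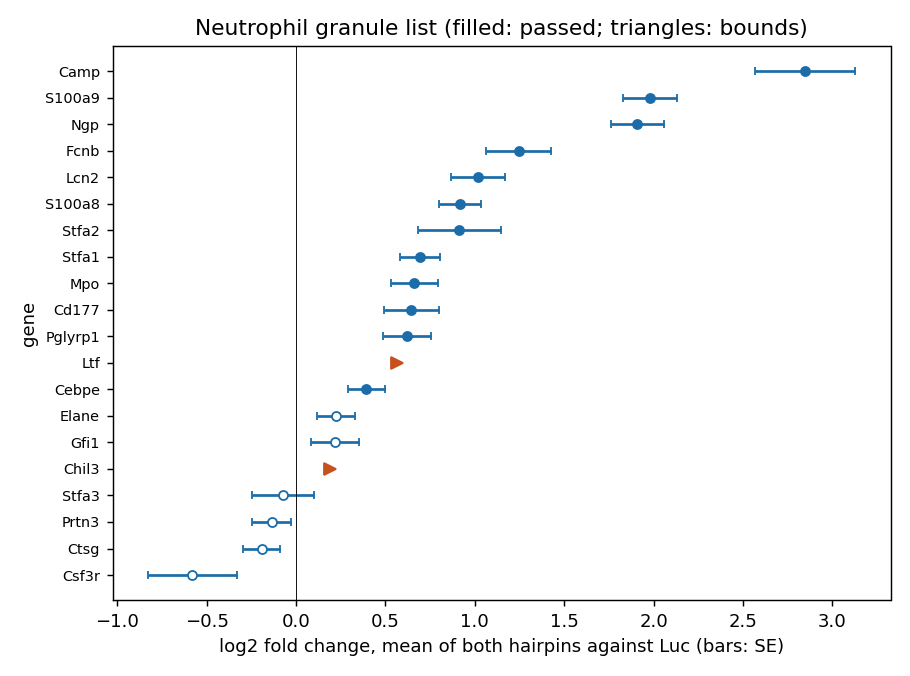
Log2 fold change of the 20 measured genes of the neutrophil granule list (horizontal axis; points are the mean of both hairpins against Luc, bars the SE, filled points passed the threshold). Triangles without a bar are the lower bounds of Ltf and Chil3, undetected on the Luc arrays, and Camp leads with 2.85.

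Across all genes, 3465 of 8027 differed between the mean of both hairpins and Luc at an adjusted p under 0.05 (limma), 1918 higher and 1547 lower, and 436 of them by over 2-fold. Beyond the granule genes, the largest rises were in Cept1, an enzyme of phospholipid synthesis (1.87), Ncf1, a subunit of the phagocyte NADPH oxidase (detected on 0 of the 3 Luc arrays, at least 2.35-fold), Nlrx1, a mitochondrial regulator of innate immunity (1.82), Irak3, an inhibitor of Toll-like receptor signalling (1.81), the phosphatase Ptpn18 (1.74), the cystatin family gene Cstdc5 (1.72) and the DNA repair gene Mgmt (1.68). Of these, Irak3 and Ptpn18 were detected on 1 and Nlrx1 and Mgmt on 2 of the 3 Luc arrays. The largest falls were in Wdr13 (-1.79), Mfge8, a bridge in the uptake of dying cells (-1.65), Ccdc65 (-1.61), Stxbp5l (-1.58), the glutamate transporter Slc1a3 (-1.58), Pdia5 (-1.54), Mtap, an enzyme of methionine salvage (-1.53), Acyp2 (-1.53), Trp53bp1, a DNA damage response protein (-1.50), and the transcription factor Cebpg (-1.49). Slc1a3 was detected on 2 of the 3 hairpin 94 arrays, and Acyp2 on 1 array of each hairpin. Standard errors of these genes lay between 0.1023 (Ccdc65) and 0.1995 (Irak3). For Mfge8, Pdia5, Mtap and Trp53bp1 the other detected probe did not fall (-0.00426, -0.0129, 0.12 and 0.31, none past the threshold), and Stxbp5l's gave -0.44. Nlrx1's other probes gave -0.11 and 0.87, the second past the threshold. The rule for single hairpins added Klf10, a transcription factor of TGF-beta signalling, for hairpin 94 (at least 2.42-fold lower, counted from the detection floor of its arrays, as it was detected on all 3 Luc arrays and on 0 of its arrays). For hairpin 97 it added Dnajc10, a chaperone of the endoplasmic reticulum (-1.78, with 0.12 from its other probe against Luc in the mean of both hairpins), and the small GTPase gene Rac1 (-1.70).

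The scaling of the arrays moved the changes of all genes together. Over all genes the median log2 fold change was 0.0518 with quantile normalization, 0.961 when arrays were scaled to a common median of all probes, and -0.475 when they were scaled over the probes detected on all arrays. These left 6111 and 5604 genes past the threshold, 99.9% and 17.6% of them higher, and cyclic loess left 2796, 44.2% higher. An array detected 20.45% to 31.54% of its probes, so the median of all probes was a background level. It was 4.376 to 4.426 in log2 after background correction, and scaling to it left the brightness difference between the groups largely in place. With the first scaling the falls of Csnk1d, Csnk1e, Sesn1, Hoxa5, Mef2c, Il3ra, Gins2, Aurka, Bag3, Ddit3, Rpl30, Junb, Ulk1 and Prg2 became values above 0, and with the second the values of Ltf, Chil3 and Wrap53 lay below 0. With the number of detected probes as a covariate limma called 0 genes, and 857 had an unadjusted p under 0.05.

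Other detected probes of the same gene measured another change in many cases. Among 281 such probes of genes that rose, with both probes detected on all 9 arrays, 60.9% had the same sign, and among 439 of genes that fell, 59% had it. The probes' errors would allow 99.4% and 99.6% if both probes measured the same change. Without the limit to all 9 arrays, the shares were 72% for genes that rose and 41.7% for genes that fell. Among genes with another detected probe, 252 of 650 that rose and 111 of 643 that fell had another probe past the threshold the same way. At an unadjusted p under 0.001 for the brightest probe, 62% of 384 probes detected on all 9 arrays had the same sign.

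The list of p53-activated genes did not stand apart from the other genes in knockdown cells. Of 35 measured members, 12 rose and 2 fell over all genes tested, and as many adjusted over the list alone, with a median log2 fold change of 0.326, or 0 with the 9 genes undetected on all Luc arrays at their lower bound. Camera gave an adjusted p of 0.415 (0.48 with an estimated correlation). The fry test, which asks whether the members move on balance one way without comparing them with other genes, gave an adjusted p of 0.000106. Zmat3, an RNA-binding p53 target, was detected on 0 of the 3 Luc arrays and was at least 1.56-fold higher in the mean of both hairpins. Its mean log2 value was 6.215 with hairpin 94 and 4.954 with hairpin 97, so that bound rests mainly on hairpin 94. Wrap53, an antisense partner of p53 in the genome, was undetected there too and was at least 1.34-fold higher. Mgmt rose (above), Bbc3, the apoptosis inducer Puma, rose by 0.86 (SE 0.1748, adjusted p = 0.003109), and the DNA repair gene Ddb2 rose by 0.78. The other probe of Bbc3 gave -0.16. Sesn1 fell by 0.88, while its other probe gave 0.20, and Cd80 fell by 0.69 (adjusted p = 0.01504, detected on 2 of the 3 Luc arrays and on 1 of the 6 knockdown arrays). Several well-known targets did not pass with their brightest probe: the cell cycle inhibitor Cdkn1a gave -0.05, Mdm2, the ubiquitin ligase that limits p53, gave -0.24, and Ccng1 gave -0.19. Mdm2 passed as lower in 4 of the alternatives (-0.696 to -0.185). The other probes of these genes differed from them: those of Ccng1 passed as higher (1.23 and 1.45), that of Mdm2 as lower (-0.70), and those of Cdkn1a gave 0.50 (passing) and -0.01. The 19 other probes of 14 genes of the list had a median of 0.443, against 0.2 for such probes of all genes, and about at the 0.441 that as many random probes allow (their median plus 2 standard errors). Over only probes detected on all arrays the list's median was -0.123, and over arrays scaled to the probes detected on all of them it was -0.259, above the median of all genes under that scaling (-0.475). With the number of detected probes as a covariate it was 0.0929. With hairpin 94 alone against Luc the median was 0.399 (camera adjusted p = 0.11, and 0.398 with an estimated correlation). It passed without Luc replicate 1 (median 0.446), with every detected probe tested (0.401) and with the mean of a gene's probes (0.403). With hairpin 97 alone it was 0.117 (camera adjusted p = 0.745).

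Genes of beta-catenin signalling and of the leukemia program had medians near 0 as groups. Of 8 measured beta-catenin target genes, from 25 listed, 0 passed in limma in either direction, and 0 at an unadjusted p under 0.05. Of 17 measured genes of the MLL-AF9 and self-renewal list 0 rose and 2 fell (1 adjusted over the list alone; 0 and 4 at an unadjusted p under 0.05 by limma), with a median of 0.00619, or 0 with the 1 gene undetected on all Luc arrays at its lower bound. The falls were in Hoxa5, a homeobox gene of the MLL-AF9 program (-1.12, SE 0.1279), and the transcription factor Mef2c (-0.66, SE 0.2143), whose 4 other probes ranged from -0.50 to 0.33, the last of them past the threshold as higher. Hoxa9 (-0.18) and Meis1 (0.24), partners in the same program, did not pass, nor did Kit, the receptor used in the sort (-0.32). For the MLL-AF9 and self-renewal list fry gave an adjusted p of 0.0516 (downward) and camera 0.572. With hairpin 97 alone 0 of its genes rose and 3 fell, with a fry adjusted p of 0.0274 (downward) and a camera adjusted p of 0.379. The genes of the sort gate and stem cell surface gave 3 rises and 2 falls of 9 (3 and 3 adjusted over the list alone), with Fcgr3, an Fc receptor of the granulocyte-macrophage progenitor gate, higher by 1.12 (SE 0.1406), and Il3ra, the interleukin-3 receptor subunit, lower (-0.74, SE 0.1762).

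Cell division, apoptosis, stress and metabolism lists held rises and falls side by side, and none stood apart from the other genes with camera under the filter, background correction and normalization used throughout. Of 37 DNA replication and E2F target genes 17 rose and 5 fell (19 and 7 adjusted over the list alone), among them the ribonucleotide reductase subunit Rrm2 (1.30), the helicase subunit Mcm3 (0.78) and the replication factor Gins2 (-0.76, with 0.52 and 0.64 from its other probes, the second past the threshold). Of 32 G2/M and mitosis genes 11 rose and 5 fell (12 and 5 adjusted over the list alone), such as the condensin subunit Ncapd2 (0.93) and the mitotic kinase Aurka (-0.58). Of 16 apoptosis-promoting genes 5 rose and 3 fell, among them Bad (1.08) and Casp9 (0.815, with -0.0472 from its other probe). Of 12 apoptosis-opposing genes 6 rose and 1 fell, with Mcl1 (1.35, SE 0.1387) and the chaperone regulator Bag3 (-1.11, SE 0.1286) at the extremes. In the list of the integrated stress and unfolded protein responses 7 of 25 rose and 4 fell. Its regulator Atf4 rose by 1.28 and the asparagine synthetase gene Asns by 1.01, while Ddit3 fell by 1.18 with another probe past the threshold as higher (0.33). Of 30 ribosomal protein genes 14 rose and 4 fell (16 and 4 adjusted over the list alone), including Rpl26 (1.43), Rpl12 (1.11) and Rpl30 (-1.03, with 0.08 from its other probe). Counts adjusted over the list alone were the same as over all genes for the apoptosis and stress lists. The adjusted p with camera was 0.352 for the replication list, 0.536 for G2/M, 0.931 and 0.519 for the apoptosis lists, 0.931 for the stress list and 0.241 for ribosomal proteins. The replication median was 0.32, or 0.276 with its 3 genes undetected on all Luc arrays at their lower bound, and the list passed camera without the detection filter (0.275) and with both median scalings (1.47 and 0.0369). The stress list passed with scaling over the probes detected on all arrays (-0.0981), a median above that of all genes under this scaling. The ribosomal median was 0.296. That list passed without the detection filter (0.175), over probes detected on all arrays (0.296), without background correction (0.271), with the series matrix values (0.287), with both median scalings (1.69 and 0.25) and with cyclic loess (0.295).

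The remaining lists gave no camera call either under these settings. Under both median scalings 3 of them passed camera: Myc targets (medians 1.32 and -0.117), oxidative phosphorylation (1.42 and -0.0162) and lysosome and autophagy (1.34 and -0.0944), the first of each pair with all probes and the second with probes detected on all arrays. Each of these medians lay above that of all genes under the same scaling. Rises and falls numbered 8 and 4 of 33 for Myc targets and ribosome biogenesis, 5 and 2 of 17 for the interferon response, 2 and 1 of 10 for NF-kB and inflammatory genes, 4 and 3 of 12 for heat shock, 2 and 3 of 9 for immediate early genes, 9 and 3 of 22 for glycolysis and hypoxia (10 and 3 adjusted over the list alone), 12 and 9 of 33 for oxidative phosphorylation, 3 and 5 of 15 for cholesterol synthesis and 6 and 6 of 23 for lysosome and autophagy (7 and 6 adjusted over the list alone). Except where given, the counts adjusted over the list alone were the same. Within these lists the immediate early gene Junb fell by 1.23 (SE 0.1311), the glycolytic enzyme genes Aldoa and Pgk1 rose by 1.41 and 0.93, the protease gene Ctsb rose by 1.19 and the autophagy kinase gene Ulk1 fell by 0.99. Among markers of other cell types, 4 of 9 monocyte and macrophage genes rose and 0 fell in limma (5 and 0 at an unadjusted p under 0.05; camera adjusted p = 0.334), led by the lysozyme gene Lyz1 (1.49, SE 0.1045), with Lyz2 at 0.37. In the T and NK list 0 of 5 rose and 1 fell in limma (0 and 2 at an unadjusted p under 0.05), and in the mast cell, basophil and eosinophil list 2 of 6 rose and 2 fell (2 and 3 adjusted over the list alone), among them the granule protein gene Prg2 (-1.18, SE 0.1454). Lists with under 5 measured genes were not tested: of 4 class II and dendritic genes 1 fell, of 4 stromal and endothelial genes 1 rose, and of the 2 erythroid, 3 megakaryocyte and 1 B lineage genes 0 passed in limma and 0 at an unadjusted p under 0.05.

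Both hairpin groups differed from the shared Luc arrays in many of the same genes. Hairpin 94 changed 2847 genes (1574 higher, 1273 lower) and hairpin 97 changed 2888 (1598 higher, 1290 lower), and 1205 were higher and 987 lower with both, while 1 went opposite ways. With scaling to the median of all probes hairpin 94 changed 5836 and hairpin 97 5826 genes, 99.9% of them higher each time, and with scaling over the probes detected on all arrays 5093 and 5289, of which 17.1% and 16.5% were higher. With the replicate block, fitted to only the Luc and hairpin 94 arrays, hairpin 94 changed 1732, against 2033 in such a fit without the block. Camp (2.56 with hairpin 94, 3.14 with hairpin 97), S100a9 (2.00 and 1.96), Ngp (1.83 and 1.99), Wdr13 (-1.88 and -1.70) and Mfge8 (-1.65 and -1.64) were among the genes changed the same way by both. Independent lists of these sizes would share 313.3 higher and 204.6 lower genes. The fold changes correlated across genes with r = 0.8998 against 0.4995 in 100 simulations of unchanged groups with shared controls, and 87.79% had the same sign against 66.66%. The covariance was 0.2584 against 0.01901, a difference of 0.2394. Genes are not independent replicates, and with 3 control arrays the controls could not be split. The simulated groups had no brightness difference, so part or all of the excess may come from the shared, dimmer Luc arrays.

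**Figure D3:**
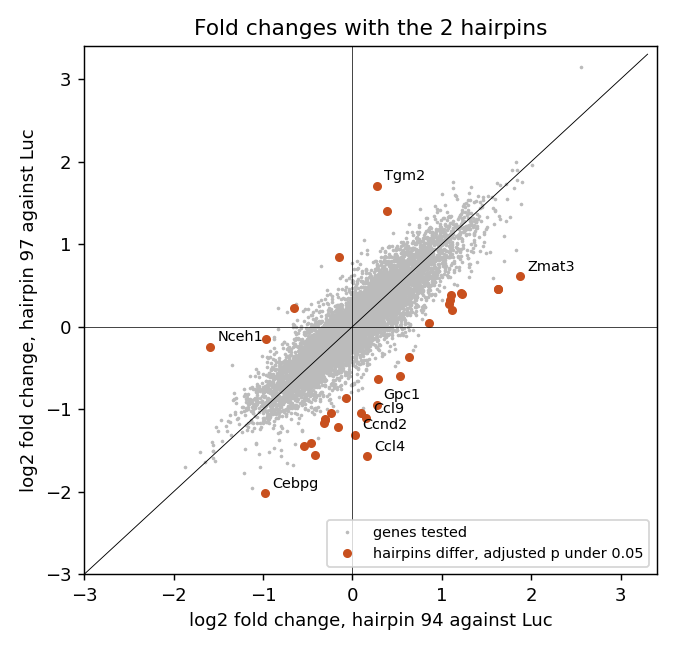
Log2 fold change of each gene tested with hairpin 94 (horizontal axis) and hairpin 97 (vertical axis) against Luc, with the line of equal change. Colored points are the 34 genes that differed between the hairpins, such as Tgm2, Ccl4 and Zmat3, which was undetected on the Luc arrays, so that its fitted position is not a bound.

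With the spread pooled over all groups, the hairpins themselves differed in few single genes. Between hairpin 97 and hairpin 94, 34 genes passed (limma), 6 higher and 28 lower with hairpin 97, and 757 had an unadjusted p under 0.05. Higher with hairpin 97 were Tgm2, a transglutaminase (1.44, SE 0.1643, adjusted p = 0.007421), the cholesteryl ester hydrolase Nceh1 (1.35), the vesicle fusion protein Vamp7 (1.01, detected on 2 of the 3 hairpin 94 arrays), Tmem199 (1.00) and the nuclear export factor Nxt2 (0.89). Lower with hairpin 97 were the chemokine genes Ccl4 (-1.73, SE 0.2208, adjusted p = 0.01066) and Ccl9 (-1.26), the D-type cyclin gene Ccnd2 (-1.34), Zmat3 (-1.26, SE 0.1375, adjusted p = 0.007421) and the cell surface proteoglycan gene Gpc1 (-1.22). Cebpg, named above, was also lower (-1.04, SE 0.1707, adjusted p = 0.03318). The other probes of Ccl4 and Ccnd2 gave -0.56 and -0.68. The count rested on every knockdown array: leaving out hairpin 94 replicate 1, 2 or 3 left 3, 16 or 0 genes (476 at an unadjusted p under 0.05 for the last), and leaving out hairpin 97 replicate 4, 5 or 6 left 5, 1 or 2. A fit to the 6 knockdown arrays alone called 152 genes, so the count of 34 depends on the pooled spread. That spread includes the Luc arrays, which correlated less with each other (r = 0.9619 to 0.967). Arrays within hairpin 94 gave 0.9845 to 0.9886, and within hairpin 97 0.9902 to 0.9912. Against Luc, fits to only the groups compared called fewer genes: 2033 for hairpin 94 and 2521 for hairpin 97, against 2847 and 2888.

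Cell division genes were higher as a group with hairpin 97 than with hairpin 94, and p53-activated genes were lower with the preset correlation only (adjusted p = 0.054 with an estimated correlation). Of 32 G2/M and mitosis genes 30 had a higher mean with hairpin 97, with a median log2 difference of 0.272 (camera adjusted p = 3.76e-10, adjusted p = 0.0297 with an estimated correlation). The largest differences in this list were in Top2a, the mitotic topoisomerase (0.62, SE 0.1479), the spindle protein Nusap1 (0.61, SE 0.1714) and Birc5, the survivin gene (0.58, SE 0.1618), and the mitotic kinase genes Cdk1, Aurkb and Plk1 gave 0.45, 0.46 and 0.46. Over all genes tested 0 members passed in limma (14 higher and 0 lower at an unadjusted p under 0.05), and 5 passed adjusted over the list alone. Under alternatives Top2a passed in 7 settings (0.486 to 0.62), Plk1 in 3 (0.317 to 0.463) and Nusap1 with only the groups compared (0.608) and with array weights (0.596). Against Luc, 11 genes of the list rose and 1 fell with hairpin 97 (13 and 1 adjusted over the list alone; median 0.269, camera adjusted p = 0.0695), and 3 rose and 5 fell with hairpin 94, over the list alone too (median 0.0312, camera adjusted p = 0.948). Both other probes of Top2a gave differences near 0 (0.06 and -0.07). Of 37 DNA replication and E2F target genes 29 had a higher mean with hairpin 97, with a median of 0.202 (camera adjusted p = 0.000224, adjusted p = 0.0297 with an estimated correlation), such as Rrm2 (0.60, SE 0.2946) and the cyclin gene Ccne2 (1.09, SE 0.289), and 0 members passed in limma, adjusted over the list alone too (5 higher and 0 lower at an unadjusted p under 0.05). Ccne2 passed in 4 of the alternatives (0.958 to 1.19), and Rrm2 with only the groups compared (0.605). Against Luc, 16 replication genes rose and 4 fell with hairpin 97 (20 and 4 adjusted over the list alone; median 0.411, camera adjusted p = 0.0695), and 12 rose and 8 fell with hairpin 94 (17 and 9; median 0.292, camera adjusted p = 0.849). Over only the other probes the replication call ended, with a median of 0.173. Of 35 p53-activated genes 24 had a lower mean with hairpin 97, with a median of -0.193 (camera adjusted p = 0.00282), a call that missed the threshold with the estimated correlation (adjusted p = 0.054 with an estimated correlation). Without background correction and with the series matrix values, the medians were 0.148 and 0.138 for G2/M, 0.102 and 0.0911 for replication and -0.0629 and -0.0569 for the p53 list. Without the detection filter the p53 median was -0.1. Zmat3 was the 1 member that passed, over all genes tested and adjusted over the list alone. Cdkn1a gave -0.44 with -0.61 and -0.37 from its other probes, Ccng1 gave -0.36 with -0.74 and -0.46, and Mdm2 gave -0.26 with -0.18. Cdkn1a passed without background correction (-0.299) and with the series matrix values (-0.28). The p53 call ended over probes detected on all arrays, where the median was -0.121, and over only the other probes, where it was -0.107.

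**Figure D4:**
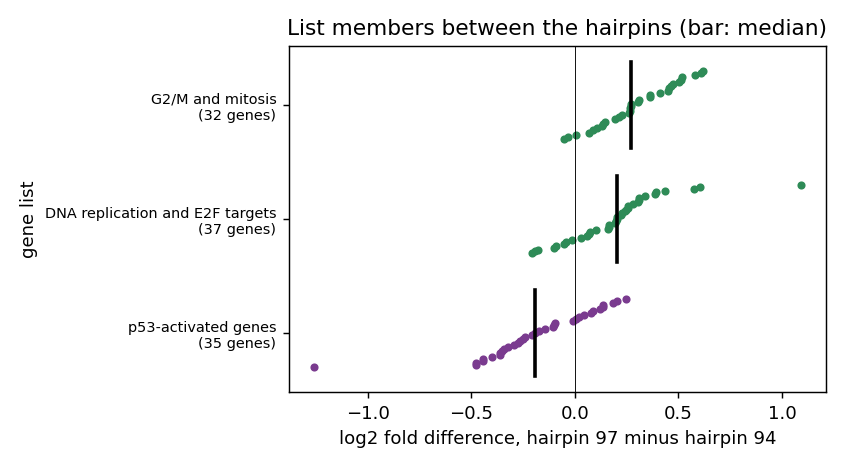
Log2 fold difference between hairpin 97 and hairpin 94 (horizontal axis) of each measured gene of 3 lists, ordered by size within a list, with a bar at the median. The G2/M median lies at 0.272, the replication median at 0.202 and the p53 median at -0.193.

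Further lists differed between the hairpins with the preset correlation only. Interferon response genes were lower with hairpin 97 (median -0.189, camera adjusted p = 0.0174, adjusted p = 0.0971 with an estimated correlation), where Oas1g, an antiviral oligoadenylate synthetase, was the 1 of 17 that passed (-0.81, SE 0.1442). It was chosen for naming after its value was seen. The call ended without the detection filter, over probes detected on all arrays and over only the other probes (medians -0.0475, -0.143 and -0.175). The median was -0.103 without hairpin 94 replicate 3, -0.0547 without background correction and -0.0457 with the series matrix values. The mast cell, basophil and eosinophil genes were also lower (median -0.394, camera adjusted p = 0.000904, adjusted p = 0.0712 with an estimated correlation), with 0 of 6 past the threshold in limma, 3 adjusted over the list alone and 3 lower at an unadjusted p under 0.05. Their median was -0.0809 without the detection filter, -0.14 without background correction and -0.109 with the series matrix values. So were 5 T and NK genes (median -0.201, camera adjusted p = 0.0443, adjusted p = 0.165 with an estimated correlation), with 0 past the threshold in limma, 1 adjusted over the list alone and 1 lower at an unadjusted p under 0.05. That call ended without Luc replicate 3 (-0.214), hairpin 94 replicate 2 (-0.144) or 3 (-0.172), or hairpin 97 replicate 4 (-0.167) or 6 (-0.224), and its median was -0.0794 without the detection filter. The neutrophil granule list did not differ past the threshold (median -0.105, camera adjusted p = 0.19; 0 genes in limma, 1 adjusted over the list alone, 2 lower at an unadjusted p under 0.05), and a difference of its size is not excluded. All 4 probes of Mpo were lower with hairpin 97 (-0.68 for the brightest, with an adjusted p of 0.1215, and -0.68, -0.51 and -0.79 for the others), and Mpo passed in 7 of the alternatives (-0.692 to -0.639).

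Other probes of a gene moved with its brightest probe in this comparison. Among 18 such probes, detected on all 9 arrays, of genes with an unadjusted p under 0.001, 100% had the same sign, and 91.2% of 80 did so at an unadjusted p under 0.01, where the errors allow 98.6% and 95.6%. Over all 1328 pairs detected on all 9 arrays the log2 differences correlated across probes with r = 0.57 and 69.9% had the same sign, as many as the errors allow. For knockdown against Luc these pairs gave 0.218 and 57.8%, where the errors allow 92%.

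**Figure D5:**
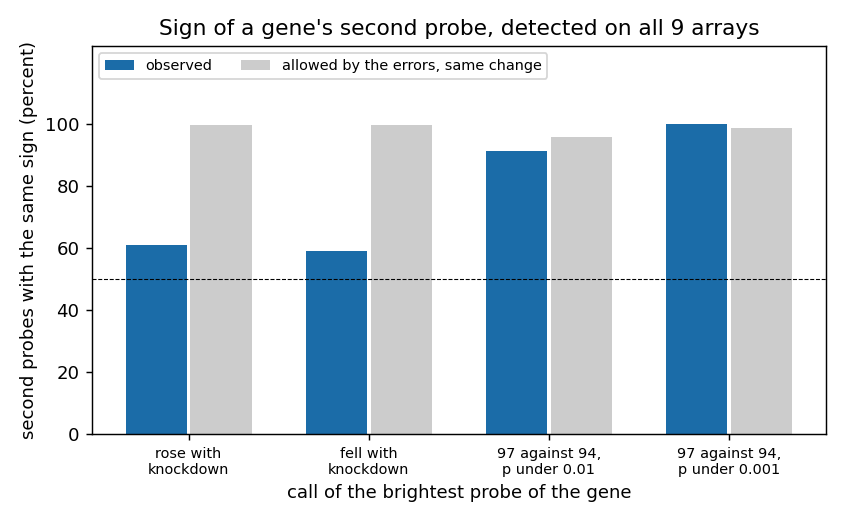
Percent of other probes of a gene with the same sign as its brightest probe (blue) and the percent that the probes' errors allow if both measured the same change (gray), for probes detected on all 9 arrays; the dashed line marks 50%. The share is 60.9% and 59% for rises and falls with knockdown, and 91.2% and 100% between the hairpins.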

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

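The tests on second probes of genes that rose, fell or differed between hairpins, of the neutrophil and of the p53 list, those averaged by gene or run on 1 cell division list, and the tests on mature neutrophils and on a linear brightness trend in the neutrophil list were chosen only after the result was seen, while those on splits of the samples, on array brightness otherwise and on second probes of cell division genes were written beforehand.

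The hairpins differed by the limma test of the difference itself in 11 genes named by rule. With hairpin 97, Tgm2 (1.44), Nceh1 (1.35), Vamp7 (1.01), Tmem199 (0.999) and Nxt2 (0.888) were higher on the log2 scale, and Ccl4 (-1.73), Ccnd2 (-1.34), Zmat3 (-1.26), Ccl9 (-1.26), Gpc1 (-1.22) and Cebpg (-1.04) were lower. Gene lists that differed by camera with the preset correlation were G2/M and mitosis (median 0.272), DNA replication and E2F targets (0.202), p53-activated genes (-0.193), interferon response (-0.189), T and NK (-0.201) and mast cell, basophil and eosinophil genes (-0.394). With an estimated correlation the first pair held, while the adjusted p was 0.054, 0.0971, 0.165 and 0.0712 for the other lists in that order. Outside the gene comparisons, 518 of the 1958 detected probes with no listed gene were higher in knockdown than in Luc arrays, and 262 were lower.

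Of the 84 splits of the 9 arrays into 6 and 3, 1, the real one, gave the 3349 genes that 6 arrays against 3 called, and the highest other gave 17. Every other split mixes Luc with knockdown arrays, and the real split also divides the arrays by brightness. The splits therefore show that the Luc arrays stand apart, but not why. They also treat the 9 arrays as independent, which the labels do not settle. Of 100 drawn splits into 3 groups, 1, the real one, gave the 2192 genes changed the same way by both hairpins. The highest other had 2100, but it kept the 3 Luc arrays together, as 3 of the 100 did, and the highest that did not had 15. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split called 2033 genes for hairpin 94, 2521 for hairpin 97 and 152 between the hairpins, and the highest other had 0 each time. For the neutrophil list 1 of the 84 splits, the real one, gave a median as large (highest other 0.454). For the cell division and p53 lists between the hairpins the 10 splits are again too few, with real medians of 0.24 and -0.193 and highest others of 0.126 and 0.109 in size.

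Part of the differences between knockdown and Luc arrays may be signals that differ by probe, not by gene: other probes detected on all 9 arrays had the sign of the brightest in 60.9% of cases for rises and 59% for falls, where the errors allow 99.4% and 99.6%. It does not account for the direction of the genes that differ most between the hairpins and have such probes. At an unadjusted limma p under 0.001, 100% of 18 such probes went the same way, though only 5.56% of them passed. For knockdown against Luc the share was 62% of 384. Between the hairpins it was 91.2% of 80 at an unadjusted limma p under 0.01, and 83.1% of 183 when detection on 3 arrays is enough. Of the genes named by rule as differing, other probes were given only for Ccl4 and Ccnd2, with smaller differences (-0.564 and -0.683). For genes without other probes the explanation stays open. The dimmer Luc signal cannot be told apart from knockdown, because the groups do not overlap in brightness; within groups, the slope on detected probes correlated across genes with the knockdown change at r = 0.13 (exact two-sided permutation p = 0.338, 216 permutations). With detected probes as a covariate limma called 0 genes (857 at an unadjusted p under 0.05), while the median SE rose from 0.148 to 0.506, the median absolute change went from 0.359 to 0.484, and the changes with and without it correlated with r = 0.591. What made probes differ, such as RNA quality, was not tested, since no probe positions were given, and a true effect of Csnk1a1 loss, which the design names, also stays open and untested.

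Single probes do not explain the rise in the 7 neutrophil granule genes that had second probes. These 11 second probes had a median of 0.69, above the 0.523 that random second probes allow (their median plus 2 standard errors). Averaged by gene it was 0.69 (0.57 allowed). Camp, S100a9, Ngp, S100a8 and Lcn2 have 1 probe each, so the test says nothing about these leading genes. A linear trend with the number of detected probes is not the whole cause either: the mean of the list relative to all genes was 0.723 with that covariate (SE 0.17) and 0.709 without it, while an effect of the dimmer Luc arrays that is not linear stays open, since the groups do not overlap. Mature neutrophils among the sorted knockdown cells, which a gate on high Kit should remove, cannot be told apart from granulocyte maturation: Csf3r gave -0.579 (SE 0.249) but was detected on only 7 of the 9 arrays, and Mmp8, Mmp9 and Cxcr2 were detected on 0, 1 and 2 arrays. An effect of Csnk1a1 loss on maturation stays open and untested, and so do monocytic cells, which the gate should remove too, although 4 of 9 monocyte and macrophage genes rose and 0 fell in limma (5 and 0 at an unadjusted p under 0.05; median 0.335, fry adjusted p = 0.000317).

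Cell division genes were higher and p53-activated genes lower with hairpin 97 than with hairpin 94, the latter with the preset correlation only (adjusted p = 0.054 with an estimated correlation). Single probes do not account for the cell division lists, where 42 second probes had a median of 0.201 (random second probes allow 0.102), or 0.186 averaged by gene (0.112 allowed); by list the gene medians were 0.286 for G2/M (0.142 allowed) and 0.173 for replication (0.153 allowed), whose camera call ended over these probes. For the p53 list, whose call ended too, they stay open, since 7 of 19 second probes were higher and their median of -0.179 (-0.0973 allowed) became -0.107 averaged by gene, at the -0.106 allowed. A covariate for detected probes gave medians of 0.239 and -0.2, against 0.24 and -0.193 without it, but decides nothing about brightness, since the groups were about equally bright (13507 ± 673 and 13544 ± 601 detected probes, SD, n = 3 each) and left it little to move. The depth of knockdown, other targets of the hairpins and groups handled apart stay open, as the Csnk1a1 probe was not detected and no batch is recorded.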

How the results depend on the processing

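Median scaling over the probes detected on all arrays, cyclic loess, the mean of all detected probes of a gene, only its other detected probes, and the number of detected probes as a covariate were chosen after seeing the data. The cause of a difference was not tested except where stated.

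With the preset correlation, the neutrophil list kept its direction and its camera call for the mean of both hairpins under every alternative, with medians of 0.348 to 1.87, and for each hairpin alone, except for hairpin 97 with only the other probes (0.701). With an estimated correlation its adjusted p was 0.0827 for the mean of both hairpins, 0.0477 for hairpin 94 and 0.139 for hairpin 97. The G2/M list kept both between the hairpins (0.138 to 0.364), and so did the mast cell, basophil and eosinophil list where it had 5 measured genes (-0.467 to -0.0809; adjusted p = 0.0297 and 0.0712 with an estimated correlation).

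With each of the 13641 detected probes tested, the counts are of probes and not of genes. Probes changed by hairpin 94, by hairpin 97, by the mean of both and by both the same way then numbered 4413, 4487, 5485 and 3342. Genes changed, in the same order, numbered 5836, 5826, 6111 and 5448 with median scaling over all probes. They numbered 5093, 5289, 5604 and 4483 with median scaling over probes detected on all arrays. With only the other probes, where fewer genes are tested, they numbered 733, 728, 947 and 544. The covariate left 0 of each by limma (885, 849 and 857 at an unadjusted p under 0.05 for the first 3), with a larger SE. Of the 3465 genes of the mean of both hairpins, 71.1% were called the same way and 502 the opposite way with median scaling over probes detected on all arrays, 54.5% and 1151 with median scaling over all probes, 81.1% with the mean of probes, 74.6% with cyclic loess and 90.6% with the series matrix values. Of 1293 with other probes, 22.7% were called the same way and 174 the opposite way by those.

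Between the hairpins, 19 probes passed with every detected probe tested. Counted as genes, 91 passed over probes detected on all arrays, 122 without background correction and 128 with the series matrix values. With only the groups compared 152 genes passed, with a trended and robust variance 78 and with array weights 160. Median scaling over probes detected on all arrays gave 83 genes, cyclic loess 180, only the other probes 1 and the covariate 18. Leaving out each array in turn gave 0 to 40 (476 at an unadjusted p under 0.05 by limma beside the 0).

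Among lists between the hairpins, camera calls were lost for p53-activated genes over probes detected on all arrays (-0.121) and only the other probes (-0.107), for replication genes over only the other probes (0.173), and for interferon genes without the detection filter (-0.0475), over probes detected on all arrays (-0.143) and over only the other probes (-0.175). The T and NK call was lost with only the groups compared (-0.201) and without Luc replicate 3 (-0.214), hairpin 94 replicate 2 (-0.144) or 3 (-0.172), or hairpin 97 replicate 4 (-0.167) or 6 (-0.224), and held without each other array, with -0.329 the farthest (without hairpin 97 replicate 5). For hairpin 94 against Luc, p53-activated genes passed camera with every detected probe (0.401) and the mean of probes (0.403), and without Luc replicate 1 (range over arrays left out 0.319 to 0.461). The p53 median turned negative over probes detected on all arrays (-0.123 for the mean of both hairpins, -0.0435 for hairpin 94). With median scaling over these probes it was -0.259 and -0.213, where the median of all genes was -0.475 and -0.455, so that the list lay above it.

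Median scaling over all probes scaled to a background level and left the brightness difference largely in place. It moved the median of all genes to 0.961 and turned these values above 0: Myc targets 1.32, Prtn3 1.06, Ctsg 1.25, Sesn1 0.57, Cdkn1a 1.4, Mdm2 1.18, Ccng1 1.26, Hoxa5 0.296, Mef2c 0.788, Csnk1d 0.539, Gins2 0.654, Aurka 0.815, Rpl30 0.325, Ddit3 0.19, Kit 1.13, Hoxa9 1.26, Il3ra 0.679, Junb 0.194, Bag3 0.341, Csnk1e 0.675, Ulk1 0.438 and Prg2 0.259. Median scaling over probes detected on all arrays, which moved that median to -0.475, turned below 0 the integrated stress response (-0.0981), oxidative phosphorylation (-0.0162) and lysosome lists (-0.0944), and Ltf (-0.129), Chil3 (-0.462) and Wrap53 (-0.275). Each of these values still lay above the median of all genes. The mean of probes reversed Ccng1 (0.831) and Gins2 (0.136). Only the other probes reversed Mtap (0.12), Trp53bp1 (0.309), Bbc3 (-0.158), Sesn1 (0.203), Ccng1 (1.34), Gins2 (0.582), Rpl30 (0.0837), Ddit3 (0.332), Casp9 (-0.0472), Csnk1e (0.268) and Dnajc10 (0.119). The covariate reversed Bbc3 (-0.0318), Mef2c (0.911) and Csnk1e (0.942).

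The lists for replication, Myc targets, oxidative phosphorylation, ribosomal proteins and lysosome passed camera against Luc under both median scalings, the first and the fourth also without the detection filter, and ribosomal proteins also over probes detected on all arrays, without background correction, with the series matrix values and with cyclic loess.

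Single genes also gained calls. Between the hairpins these were Top2a (0.486 to 0.62, 7 settings), Mpo (-0.692 to -0.639, 7), Ccne2 (0.958 to 1.19, 4), Plk1 (0.317 to 0.463, 3), Nusap1 (0.596 and 0.608), Cdkn1a (-0.299 and -0.28) and Rrm2 (0.605, 1). Against Luc, for the mean of both hairpins, they were Elane (0.223 to 1.62, 4), Meis1 (1.69, 1), Mdm2 (-0.696 to -0.185, 4), Ctsg (-0.213 and -0.197), Csf3r (-1.22 and -0.609) and Prtn3 (-0.371, 1).

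Sign changes of single genes and of other lists that passed in neither setting are not counted as reversals, and they numbered 12 with median scaling over probes detected on all arrays, 8 with the covariate, 6 with only the other probes, 6 without the detection filter and at most 4 in each other setting.

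With the replicate block, the number shared by Luc and hairpin 94, hairpin 94 changed 1732 genes, and no camera call of the p53 or neutrophil list changed. A fit to the same arrays without the block called 2033. Deviations of arrays of the same number correlated across genes with r = 0.0634, 0.0505 and 0.141. Those of different numbers were mostly below 0 (down to -0.126), but hairpin 94 replicate 2 correlated best with Luc replicate 1 (0.0706). The fit without pairs was fixed beforehand, and whether the numbers mark pairs stays open. Alternatives for Csnk1a1 were not run, since its probe was not detected, and a block for the slide could not be fitted, since no slide is named. Signal over background limits the comparison with Luc, whose arrays detected 3570 fewer probes.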
